A study of Xenopus laevis with 9 samples.

How the data were processed

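Total RNA of XLK-WG cells was measured on 9 Affymetrix Xenopus arrays, 3 each after 3 h with DMSO vehicle, 100 nM TCDD or 100 nM FICZ. Per the labels, RNA was purified with RNeasy kits, labelled with biotin by the MessageAmp II kit, and the replicates are biological. The submitters' notes name GCOS, the scanner maker's software, without a version. The algorithm, the scaling target and any log step are not given in the sources used here. The deposited values are on a log2 scale with a floor of 0. The log base was read from the values: the highest, 13.627, is 12651 as a linear signal if log2, whereas a natural log would give 828192, beyond the range of a scanner. Between 20 and 52 probe sets per array sat at the floor. Detection calls were not used here, so it is unknown which probe sets lay above background. For arrays no read depth exists, and the number of arrays limits the precision.

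Of 15611 probe sets, 120 were controls and were left out of the tests. Of the other 15491, 9304 carried 1 gene symbol, 195 several and 5992 none, by the platform annotation, and 9227 of the first were matched by gene identifier to a Xenopus laevis reference gene table, with 2 symbols updated. They stand for 7531 genes. Probe set positions are not given in the sources used here, so no coordinates are reported. AHR itself, AHRR, tiparp, nqo1 and cyp1b1 had no named probe set here.

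The groups, tests, filters, lists and most alternatives were fixed before the data were examined. By that plan the deposited values were to be kept if trimmed means of the linear signal (2% trimmed at each end) lay within 5% of each other or medians within 0.1 on the log2 scale. The trimmed means ran from 293.6 to 332.7, a ratio of 1.13, and the medians differed by 0.2, so the values were quantile normalized. Probe sets with a mean under the 25th percentile (log2 4.88) were not tested, which left 11618. limma 3.58.1 in R 4.3.3 fitted a mean per group to all 9 arrays (lmFit, then eBayes with trend=TRUE; 6 residual and 7.82 prior degrees of freedom), with contrasts for TCDD against DMSO, FICZ against DMSO, FICZ against TCDD and the mean of both ligands against DMSO. P values were two-sided and adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot reach a p under 0.1, so the test rests on the variance shared across probe sets. The median SD within groups was 0.17. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were prepared with pandas 2.3.3 and numpy 2.4.6.

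The 22 gene lists were AHR target genes, AHR pathway components, phase I and II metabolism and transport, NRF2 and oxidative stress, heat shock response, ER stress and amino acid response, immediate early and growth factor response, cell cycle and proliferation, p53 and DNA damage response, inflammation and innate immunity, extracellular matrix and TGF-beta response, circadian clock, sterol and fatty acid metabolism, hypoxia response, thyroid hormone and retinoid response, ribosomal proteins, mitochondrial respiratory chain, proteasome, kidney epithelial markers, fibroblast markers, endothelial and blood cell markers, and muscle and nerve markers. Members were matched by symbol without the copy suffix or else by a synonym, as mcm3 was to zmcm3.L and wee1 to wee2.L and wee2.S, and 18 matches through synonyms judged to belong to other genes were left out. The probe set with the highest mean stood for each of 6114 genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists, and again with an estimated correlation and with fry. Each list was also adjusted alone, over its own tested genes.

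Named genes followed a rule. In each comparison the text names up to 12 rises and 12 falls with 1 gene name, past the threshold and without overlap between arrays, taken by size. Where fewer than 5 passed, the 5 smallest p values were added and said not to pass. All measured members of the AHR target and AHR pathway lists, up to 4 members by smallest p of each other list, and up to 2 probe sets without a single name per direction could be given as well, here by their change. Of the AHR target list, ido1.L and ugt1a6.S lay under the filter and were not tested.

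The procedure was tested on simulated data with the same levels and independent noise, in which 67 probe sets were changed 1.5-fold, 67 2-fold and 66 4-fold. In the order of the contrasts given above, 52.2%, 58.2%, 58.2% and 82.1% of the 1.5-fold changes and 92.5%, 89.6%, 95.5% and 97% of the 2-fold changes were called, with 9, 5, 13 and 16 false calls. A list moved by 0.3 on the log2 scale was called, and 0 of the other lists. For the likeness of the responses and for the lists, 100 experiments without any change were also simulated, each array being a random normal mixture of the 6 residual directions of the fit, which keeps the spread of each probe set and the correlation between probe sets. Exchanging residual arrays was tried first and gave degenerate draws, because the residuals of a group add up to 0.

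Alternatives were the values as deposited, median centring, cyclic loess, other filters, other variance priors, other thresholds, a fit of only the groups compared, a replicate block, a per-probe-set test without a shared variance prior, and each array left out in turn. Array weights and leaving out the second DMSO and second FICZ arrays together were added after the data were seen. A different pseudocount was not run, because the values were already logged.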

Results

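Expression was measured in XLK-WG cells, a line derived from kidney of the frog Xenopus laevis, after 3 h with 100 nM TCDD, 100 nM FICZ or the solvent DMSO at 0.25%. TCDD is a dioxin and FICZ a photoproduct of tryptophan, and both are ligands of the aryl hydrocarbon receptor (AHR), a transcription factor whose best known target is the cytochrome P450 gene cyp1a1. The series asks how this frog line responds to the pair of ligands. Each of the 3 groups had 3 arrays, which the labels call biological replicates, and 11618 probe sets were tested. Xenopus laevis carries many genes as a pair of copies, named .L and .S. Array medians lay between 6.67 and 6.87 on the log2 scale before normalization. The arrays give no read depth, and their number, 3 per group, limits the precision. The median standard error of a log2 change between 2 groups was 0.14. DMSO replicate 2 held 22.6% of the variation within groups and stood apart on the first principal component, and FICZ replicate 2 stood apart on the second. The FICZ samples are numbered 1 to 3 in their titles and 3 to 5 in their descriptions, and the titles were used. The titles of the DMSO arrays carry a tag, CH, that the ligand titles lack and whose meaning is unknown here. Whatever it marks goes with the control group in every comparison with DMSO.

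The comparison of TCDD with DMSO asks which transcripts the dioxin changed within 3 h. Both copies of cyp1a1 rose. The log2 signal of cyp1a1.L was 6.65 ± 0.35 (SD, n = 3) with DMSO and 9.75 ± 0.53 (SD, n = 3) with TCDD, an 8.62-fold rise with a log2 change of 3.11 (SE 0.21) and an adjusted p of 1.1e-05. cyp1a1.S went from 6.42 ± 0.39 to 8.55 ± 0.61, a 4.38-fold rise with an adjusted p of 0.0026. A probe set without a gene name rose 2.03-fold, with an adjusted p of 0.0011. These 3 probe sets were the ones that passed the limma test at an adjusted p of 0.05, all higher with TCDD in 3 of 3 arrays. No probe set was called lower by limma, although 145 lower probe sets had an unadjusted p under 0.05, and a per-probe-set test without a shared variance prior called 0 in either direction. eBayes without the variance trend kept cyp1a1.L alone (adjusted p 0.0034; 0.10 for cyp1a1.S and 0.075 for the unnamed probe set). limma with array weights, an alternative chosen after the data were seen, called 22, of which 16 were higher and 6 lower. The named probe sets next in order of p did not pass. They were egln3.L, which encodes a prolyl hydroxylase that acts on hypoxia-inducible factors (log2 change 0.61, adjusted p 0.20), gjc1.L, which encodes a gap junction protein (0.91, adjusted p 0.62), and egln3.S (1.12, adjusted p 0.72). At an unadjusted p under 0.05 there were 398 probe sets, against 580.9 that chance would give. The 3 arrays of each group did not overlap in 908 probe sets, or 7.81%, against the 10% that chance gives for 3 against 3. Leaving out DMSO replicate 2 raised the count of called probe sets to 7, and leaving out DMSO replicate 3 raised it to 5.

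Among the AHR target genes, 2 of 6 tested rose with TCDD, both copies of cyp1a1, and the same 2 rose when adjusted over the list alone. The other members did not pass: gsta1.L changed by 0.27 on the log2 scale, gsta1.S by 0.26, aldh3a2.L by 0.17 and slc7a5.L by -0.19. The list stood above the other genes by camera (adjusted p 8.4e-06, and adjusted p = 0.33 with an estimated correlation). By fry, which tests the members against no change, it did not pass (adjusted p 0.087). None of the 17 tested AHR pathway components passed by limma, and 0 of them had an unadjusted p under 0.05. Of these, arnt.L, the partner of AHR on DNA, changed by 0.25, and hsp90ab1.S, a chaperone of the receptor, by -0.02. In the remaining lists no gene passed over all genes. The 21 lists without a called gene held 691 genes, of which 27 had an unadjusted p under 0.05 against 34.5 by chance. Of the hypoxia response, egln3.S was past the threshold when adjusted over the list alone, from a DMSO mean below the filter level. camera placed NRF2 and oxidative stress genes higher (adjusted p 0.049; adjusted p = 0.64 with an estimated correlation), mitochondrial respiratory chain genes higher (0.022; adjusted p = 0.64 with an estimated correlation) and cell cycle and proliferation genes lower (0.022; adjusted p = 0.64 with an estimated correlation). Over 19 refits these adjusted camera p values ranged from 0.0042 to 0.648 for NRF2, from 2.0e-05 to 0.596 for the respiratory chain and from 0.00049 to 0.767 for the cell cycle. The NRF2 call ended without DMSO replicate 2 (0.61), DMSO replicate 3 (0.068) or TCDD replicate 1 (0.64), and the cell cycle call without DMSO replicate 2 (0.20), DMSO replicate 3 (0.051) or TCDD replicate 1 (0.77). The respiratory chain call ended without DMSO replicate 2 (0.60, with the direction turned to lower) or TCDD replicate 2 (0.27). With cyclic loess the NRF2 (0.091) and respiratory chain (0.063) calls ended, and with a filter at the 50th percentile the NRF2 call (0.075).

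The comparison of FICZ with DMSO asks the same of the tryptophan product. FICZ raised cyp1a1.L 28.2-fold, from 6.65 ± 0.35 (SD, n = 3) to 11.47 ± 0.05 (SD, n = 3), with a log2 change of 4.82 (SE 0.21) and an adjusted p of 3.2e-08, and cyp1a1.S 6.49-fold to 9.12 ± 0.14 (adjusted p 5.3e-05). Rises of 2-fold or more were also seen in syne1.L, which encodes a nuclear envelope spectrin repeat protein (6.96-fold, log2 change 2.80, adjusted p 1.9e-05), gjc1.L (5.17-fold, 2.37, 2.1e-05) and sbk1l.L (2.90-fold, 1.54, 0.00070). pecam1.L, a cell adhesion gene of endothelium, rose 2.55-fold from 6.60 ± 0.12 to 7.95 ± 0.20 (adjusted p 0.00010). daam1.S, a formin gene, rose 2.12-fold, pmp22.S, a membrane protein gene, 2.11-fold, and rab40b.L, a small GTPase gene, 2.1-fold. The transcription factor genes dbp.L and jund.S rose 2.40-fold (adjusted p 0.027) and 2.17-fold (0.034), and fam102a.L rose 2.06-fold (0.049). The folds of dbp.L, with a DMSO mean of 4.67, and syne1.L, with one of 4.97, are uncertain in size, because these levels lie below or close to the filter of 4.88 and were not shown to be above background. Falls were smaller. mcm10.L and mcm5.L, which encode proteins of DNA replication, fell by 0.62 and 0.52 on the log2 scale (adjusted p 0.039 and 0.041), cdca7.L, a cell division cycle associated gene, fell by 0.56, rdh10.L, a retinol dehydrogenase gene, fell by 0.53 (0.0069), kalrn.L fell by 0.48 and dkc1.L, which encodes dyskerin, fell by 0.33. Among probe sets without a single gene name, the pair with the largest rises rose 7.13-fold and 6.43-fold (the latter from a DMSO mean of 4.94), and the pair with the largest falls fell by 1.34 and fell by 0.80 on the log2 scale.

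In all, 70 probe sets passed by limma with FICZ against DMSO, 61 higher and 9 lower, and 41 of them carried 1 gene name, for 40 genes. In each of the 70, all 3 FICZ arrays lay beyond all 3 DMSO arrays, and over all tested probe sets 1423 (12.2%) were separated in this way against 10% by chance. At an unadjusted p under 0.05 there were 858 probe sets against 580.9 by chance. Other probe sets of the same gene did not pass for gjc1.L (0.09), rab40b.L (0.36) and sbk1l.L (6 others, from -0.29 to 0.33), nor for kalrn.L (-0.57) and dkc1.L (-0.28 and -0.09). A per-probe-set test without a shared variance prior called 0 probe sets, limma with array weights 154 (114 higher and 40 lower), and eBayes without the variance trend 40, of which 2 were lower. The last did not call jund.S (adjusted p 0.14), fam102a.L (0.18), mcm10.L (0.069), mcm5.L (0.12), cdca7.L (0.11), kalrn.L (0.11), dkc1.L (0.27) or the unnamed probe set that fell by 0.80 (0.15). The count was 26 without FICZ replicate 1, 29 without FICZ replicate 2, 31 without FICZ replicate 3 and 41 without DMSO replicate 1. cyp1a1.L, cyp1a1.S, syne1.L, gjc1.L, sbk1l.L, pecam1.L, daam1.S and pmp22.S passed in each of the 10 refits run for named genes. The calls of jund.S, fam102a.L, mcm5.L and cdca7.L ended without any 1 of the 6 arrays, with highest adjusted p values of 0.18, 0.28, 0.26 and 0.22. Those of dbp.L, kalrn.L and dkc1.L ended without any FICZ array, DMSO replicate 1 or DMSO replicate 3 (0.18, 0.12 and 0.18), that of mcm10.L without any FICZ array, DMSO replicate 1 or DMSO replicate 2 (0.25), and that of the unnamed probe set that fell by 0.80 without any FICZ array, DMSO replicate 2 or DMSO replicate 3 (0.24). rdh10.L did not pass without FICZ replicate 1 or FICZ replicate 2 (0.064), nor rab40b.L without FICZ replicate 1 (0.064).

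**Figure D1:**
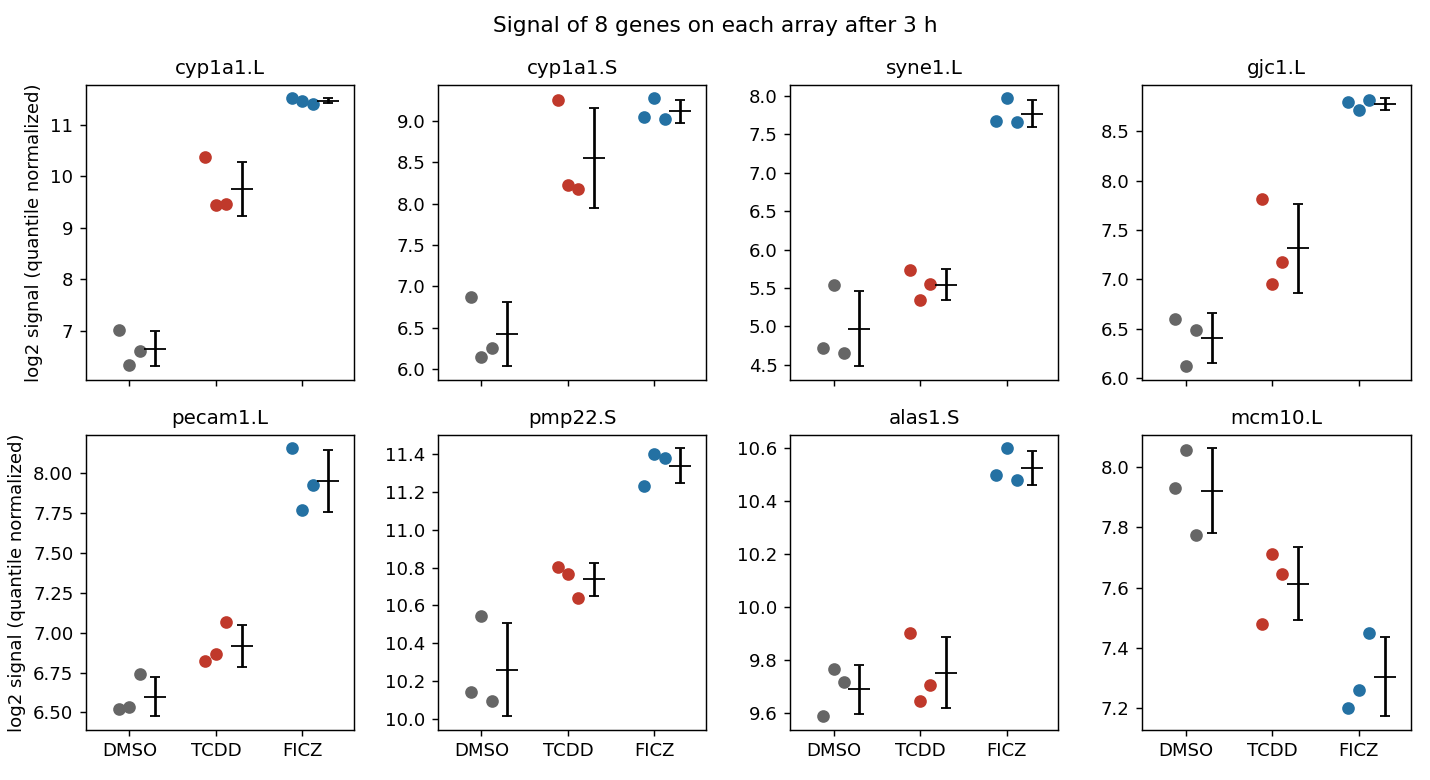
Log2 signal of 8 genes on each array after 3 h with DMSO, TCDD or FICZ. Points are arrays after quantile normalization, and bars give the mean and SD of 3 arrays. cyp1a1.L lay at 6.65 with DMSO, 9.75 with TCDD and 11.47 with FICZ, and mcm10.L at 7.92, 7.61 and 7.30.

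By list, 2 of the 6 AHR target genes rose with FICZ, again both copies of cyp1a1, and adjusted over the list alone slc7a5.L, an amino acid transporter gene, was also past the threshold, in the lower direction (-0.40, adjusted p 0.064 over all genes). aldh3a2.L (0.36), gsta1.L (0.32) and gsta1.S (0.26) did not pass. The list stood higher by camera (adjusted p 5.2e-05; adjusted p = 0.44 with an estimated correlation) than the other genes, and fry, which tests the members against no change and not against other genes, gave an adjusted p of 0.0156. Of the AHR pathway components, 0 of 17 passed by limma and 0 had an unadjusted p under 0.05. arnt.L changed by 0.03, hsp90ab1.S by 0.06, and ptges3.L, a further chaperone of the receptor, by -0.14. The median and mean of that list were positive while camera's direction was down. Of 18 genes of phase I and II metabolism and transport, 2 rose, the transporter gene abcb1.L (0.69, adjusted p 0.017) and the glutathione transferase gene gsto1.S (0.73, adjusted p 0.021). Adjusted over the list alone there were 4, with gstp1.L (0.62) and cyp4b1.L (0.63) added. The list stood higher (adjusted p 0.0013; adjusted p = 0.55 with an estimated correlation). Of 39 NRF2 and oxidative stress genes 1 rose, the glutathione peroxidase gene gpx1.L (0.26, adjusted p 0.035), and adjusted over the list alone 2 did, with sqstm1.L (0.51). That list also stood higher (adjusted p 0.00022; adjusted p = 0.55 with an estimated correlation). The call of gsto1.S ended without any FICZ array, that of abcb1.L without any FICZ array, DMSO replicate 1 or DMSO replicate 3, and that of gpx1.L without any 1 of the 6 arrays, with highest adjusted p values over the refits of 0.14, 0.15 and 0.20. Without the variance trend none of the 3 passed (0.067, 0.074 and 0.44).

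Of 90 cell cycle and proliferation genes, 1 rose with FICZ, the cyclin gene ccnd1.S (0.59, adjusted p 0.035), and 2 fell, mcm10.L and mcm5.L. Adjusted over the list alone 1 was higher and 5 were lower, among them cdc6.L (-0.57, adjusted p 0.064 over all genes), which encodes a loader of the replicative helicase. The calls of ccnd1.S (without any FICZ array, DMSO replicate 2 or DMSO replicate 3), mcm10.L and mcm5.L ended when 1 array was left out, with highest adjusted p values of 0.24, 0.25 and 0.26, and without the variance trend ccnd1.S did not pass either (0.070). The list stood lower by camera (adjusted p 0.010; adjusted p = 0.68 with an estimated correlation). The adjusted camera p ranged from 0.0073 to 0.285 over 19 refits and was 0.18 without DMSO replicate 2. Of 68 mitochondrial respiratory chain genes none passed by limma and 1 had an unadjusted p under 0.05. 55 of them had positive changes, and the list stood higher by camera (adjusted p 0.0065; adjusted p = 0.77 with an estimated correlation). Its adjusted camera p ranged from 1.3e-05 to 0.941 over 19 refits and was 0.94 without DMSO replicate 2.

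In the immediate early and growth factor list, 2 of 48 genes rose with FICZ, jund.S and zfp36l1.S (0.60, adjusted p 0.041). Adjusted over the list alone 2 were higher and 3 lower, the latter including id4.S (-0.47) and ier5.S (-0.33). In the extracellular matrix and TGF-beta list 1 of 52 rose, sparc.S (0.58, adjusted p 0.0071), and adjusted over the list alone tgfbr1.S (0.53) made it 2. dbp.L was the 1 gene of 13 in the circadian clock list that passed, and pecam1.L the 1 of 11 endothelial and blood cell markers, both also when adjusted over the list alone. In the thyroid hormone and retinoid list of 21, rdh10.L fell, and adjusted over the list alone rxra.L (0.59) was past the threshold in the higher direction. The call of zfp36l1.S ended without any FICZ array, DMSO replicate 2 or DMSO replicate 3, and that of sparc.S without FICZ replicate 1 or FICZ replicate 2, with highest adjusted p values of 0.24 and 0.067 over the refits. Without the variance trend neither passed (0.11 and 0.063). The lists of heat shock response (21 genes tested), ER stress and amino acid response (35), p53 and DNA damage response (24), inflammation and innate immunity (29), sterol and fatty acid metabolism (32), hypoxia response (38), ribosomal proteins (72), proteasome (43), kidney epithelial markers (22), fibroblast markers (11) and muscle and nerve markers (13) had no gene past the limma threshold. With the AHR pathway components and the respiratory chain, these 13 lists held 416 genes, of which 26 had an unadjusted p under 0.05 against 20.8 by chance. Adjusted over the list alone, birc2.L of inflammation (-0.57) and higd1a.L of hypoxia (0.26) were past the threshold. All 11 fibroblast markers had negative changes, with a median of -0.09, and camera gave that list an adjusted p of 0.093 (adjusted p = 0.62 with an estimated correlation). The adjusted camera p of the 17 lists that did not pass ran from 0.093 to 0.928.

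The comparison of FICZ with TCDD, at the same dose and time, asks where the ligands differed. cyp1a1.L was 3.28-fold higher with FICZ than with TCDD, with a log2 difference of 1.71 (95% confidence interval 1.25 to 2.17) and an adjusted p of 0.0025. For cyp1a1.S the difference was 0.57 (0.03 to 1.1) and did not pass (adjusted p 1.00). syne1.L was 4.68-fold higher with FICZ (adjusted p 0.00026), gjc1.L 2.75-fold, sbk1l.L 2.43-fold (0.0076) and pecam1.L 2.05-fold, with an adjusted p of 0.0030 for gjc1.L and for pecam1.L. igf1r.S, the gene of a growth factor receptor, was higher in a pair of its 3 probe sets (2.44-fold and 1.94-fold), and the other had a log2 difference of 0.98. Smaller differences were found for thbs3.L, a thrombospondin gene (1.72-fold), alas1.S, the gene of the first enzyme of heme synthesis (1.71-fold, from 9.75 ± 0.13 with TCDD to 10.53 ± 0.07 with FICZ, SD, n = 3, adjusted p 0.0019), nr3c1.L, the glucocorticoid receptor gene (1.61-fold), and pmp22.S (1.52-fold). A pair of unnamed probe sets was 6.03-fold and 3.25-fold higher, the first being the one that rose 6.43-fold with FICZ against DMSO. The unnamed probe set that fell most with FICZ against DMSO was lower, with a log2 difference of -1.13.

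Together 24 probe sets differed between FICZ and TCDD by limma, 23 higher with FICZ and 1 lower, and 11 of them carried 1 gene name. In each of the 24 the arrays of the groups did not overlap, and over all tested probe sets 1192 (10.3%) were separated against 10% by chance. At an unadjusted p under 0.05 there were 358 probe sets against 580.9 by chance. The count was 14 without FICZ replicate 1, 11 without FICZ replicate 2, 15 without FICZ replicate 3, 14 without TCDD replicate 2, 13 without TCDD replicate 3 and 41 without DMSO replicate 2, an array of neither group. A per-probe-set test without a shared variance prior called 1, limma with array weights 355 (223 higher and 132 lower, so that the balance of directions depended on the weighting), and a fit of only the groups compared 40. eBayes without the variance trend called 8, among them syne1.L, pecam1.L, thbs3.L and alas1.S, whereas cyp1a1.L (0.060), gjc1.L (0.057), sbk1l.L (0.076), both called igf1r.S probe sets (0.22 and 0.086), nr3c1.L (0.12), pmp22.S (0.31) and the unnamed probe set that was lower (0.076) did not pass, so that its 8 calls were all higher. cyp1a1.L, syne1.L, gjc1.L, pecam1.L, thbs3.L and alas1.S passed in each of the 10 refits for named genes, which kept the variance trend. Other probe sets of the same gene did not pass for gjc1.L (0.73), thbs3.L (0.21) and sbk1l.L (6 others, from -0.22 to 0.20). The call of sbk1l.L ended without FICZ replicate 2 (highest adjusted p 0.089). Those of nr3c1.L, pmp22.S and the igf1r.S probe set with the larger difference ended without any 1 of the 6 arrays, with highest adjusted p values of 0.35, 0.28 and 0.28. The other called igf1r.S probe set lost its call without FICZ replicate 1, FICZ replicate 2, TCDD replicate 2 or TCDD replicate 3 (highest adjusted p 0.12). The unnamed probe set that was lower with FICZ lost its call without FICZ replicate 1, FICZ replicate 2 or TCDD replicate 3 (highest adjusted p 0.089).

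Of the lists, AHR target genes (1 of 6 genes higher, cyp1a1.L, also when adjusted over the list alone), phase I and II metabolism and transport (0 of 18 by limma with 4 at an unadjusted p under 0.05; abcb1.L when adjusted over the list alone) and NRF2 and oxidative stress (0 of 39 by limma with 2 at an unadjusted p under 0.05) stood higher with FICZ than with TCDD by camera. Each had an adjusted p of 0.033, and with an estimated correlation adjusted p = 0.89, adjusted p = 0.89 and adjusted p = 0.92. By fry none of these lists passed, each with an adjusted p of 0.99. pecam1.L was the 1 other list member that passed. The 20 lists without a called gene held 680 genes, of which 43 had an unadjusted p under 0.05 against 34 by chance. Adjusted over the list alone, dbp.L of the circadian clock was past the threshold in the higher direction, and cdc6.L of the cell cycle and rdh10.L of the retinoid list in the lower direction. The 3 camera calls ended without FICZ replicate 1 (0.22, 0.091 and 0.13), TCDD replicate 2 (0.34, 0.43 and 0.34) or TCDD replicate 3 (0.16, 0.16 and 0.22), in that order of lists. The latter pair of lists also lost the call without FICZ replicate 3 (0.11 each), and the AHR targets without DMSO replicate 2 (0.081) or DMSO replicate 3 (0.055). With cyclic loess the AHR target and NRF2 calls ended (0.052 each), and without a filter all 3 did (0.092, 0.11 and 0.092). Over 19 refits the adjusted camera p ranged from 0.00037 to 0.344 for AHR targets and NRF2 and to 0.428 for phase I and II.

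Comparing both ligands with DMSO, as the mean of the 6 treated arrays less the 3 DMSO arrays, asks what the ligand groups had in common. cyp1a1.L (15.6-fold), cyp1a1.S (5.33-fold) and gjc1.L (3.12-fold) rose most among the named genes without overlap between treated and control arrays, with adjusted p values of 6.5e-08, 9.9e-05 and 0.00035. pecam1.L rose 1.79-fold, rab40b.L 1.74-fold, daam1.S 1.72-fold, pmp22.S 1.71-fold, fam171a1.S 1.57-fold, egln3.L 1.44-fold (adjusted p 0.045) and sparc.S, a matrix protein gene, 1.35-fold (adjusted p 0.038). The other probe sets of egln3.L changed by 0.25 and 0.24 and did not pass, nor did those of gjc1.L (-0.27) and rab40b.L (0.38). syne1.L (3.22-fold) had overlap between these arrays, falls outside the rule for named genes and was chosen after its values were seen. Among unnamed probe sets, the largest rises were 4.18-fold and 2.63-fold (the latter from a DMSO mean of 4.47, below the filter level of 4.88), whereas a pair fell by 0.78 and fell by 0.29 on the log2 scale, each of this pair with some overlap between treated and control arrays. In all 26 probe sets passed by limma, 24 higher and 2 lower, of which 14 carried 1 gene name, and 17 of the 26 had no overlap. At an unadjusted p under 0.05 there were 805 against 580.9 by chance. None of these genes other than cyp1a1.L and cyp1a1.S passed with TCDD against DMSO, and a mean over the groups can pass on FICZ alone.

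The count for both ligands was 17 without DMSO replicate 1, 13 without FICZ replicate 1, 16 without FICZ replicate 2, 14 without FICZ replicate 3 and 16 without TCDD replicate 3. It was 14 with the values as deposited, 16 without the variance trend (which did not call egln3.L, rab40b.L, sparc.S, fam171a1.S or either unnamed probe set that fell), 105 with array weights (81 higher and 24 lower) and 0 by a per-probe-set test without a shared variance prior. cyp1a1.L, cyp1a1.S, gjc1.L, daam1.S, pecam1.L, pmp22.S and the pair of unnamed probe sets with the largest rises passed in each of the 12 refits for named genes. The calls of egln3.L, rab40b.L, sparc.S and fam171a1.S ended without DMSO replicate 3, FICZ replicate 1, FICZ replicate 2, FICZ replicate 3, TCDD replicate 1 or TCDD replicate 2, with highest adjusted p values of 0.19, 0.15, 0.15 and 0.18. All but fam171a1.S also lost it without TCDD replicate 3, all but rab40b.L without DMSO replicate 1, and rab40b.L without DMSO replicate 2. The calls of the unnamed probe sets that fell by 0.78 and fell by 0.29 ended without DMSO replicate 1, TCDD replicate 3 or any FICZ array, with highest adjusted p values of 0.22 and 0.40. The first also lost it without DMSO replicate 3 or TCDD replicate 2, and the second without DMSO replicate 2 or TCDD replicate 1.

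By list, both ligands together gave AHR target genes 2 of 6 higher (adjusted over the list alone, 2 higher and 1 lower) and a higher standing by camera (adjusted p 2.1e-05; adjusted p = 0.38 with an estimated correlation) than the other genes, while fry, against no change, gave an adjusted p of 0.0155. No gene passed over all genes in phase I and II metabolism (3 higher when adjusted over the list alone; camera adjusted p 0.0032; adjusted p = 0.59 with an estimated correlation) or in NRF2 and oxidative stress (3 higher when adjusted over the list alone, among them hmox1.L of heme breakdown; camera adjusted p 0.0014; adjusted p = 0.64 with an estimated correlation). The same held for the cell cycle (1 higher and 1 lower when adjusted over the list alone; camera adjusted p 0.0032, lower; adjusted p = 0.64 with an estimated correlation) and the respiratory chain (camera adjusted p 0.0032, higher; adjusted p = 0.77 with an estimated correlation). The 19 lists without a called gene held 633 genes, of which 53 had an unadjusted p under 0.05 against 31.6 by chance. Over 19 refits the adjusted camera p ranged to 0.0649 for phase I and II, 0.194 for NRF2, 0.162 for the cell cycle and 0.898 for the respiratory chain. Without DMSO replicate 2 it was 0.15 for NRF2, 0.10 for the cell cycle and 0.81 for the respiratory chain, with the last direction turned to lower. Without DMSO replicate 3 it was 0.065 for phase I and II, and without TCDD replicate 1 it was 0.095 for the cell cycle.

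The likeness of the TCDD and FICZ responses was then measured. Both copies of cyp1a1 were called higher against DMSO with either ligand. The other probe set called with TCDD, without a gene name, was not called with FICZ against DMSO. Its mean log2 signal was 9.865 with DMSO, 10.88 with TCDD and 10.34 with FICZ, so its rise was larger with TCDD. The difference between the ligands did not pass for it. No chance level is set against that overlap of 2, because the simulations of unchanged groups had a median of 0 called probe sets and so could hardly give one, and because both comparisons share the DMSO arrays. Of the 61 probe sets that rose with FICZ, 55 had a positive change with TCDD and all 61 a smaller one, with medians of 0.88 for FICZ and 0.26 for TCDD. All 9 that fell with FICZ had a negative and smaller change with TCDD, with medians of -0.53 and -0.17. These probe sets were picked for a large FICZ change, so the comparison of sizes is not independent of that choice, and agreement in sign is expected in part from the DMSO arrays that both comparisons share. Across the tested probe sets, which are not independent replicates, the log2 changes had a Pearson r of 0.65 and a Spearman rho of 0.65, and 75.1% had the same sign, against a simulated mean of 66.7% (27.5% to 91.7%) for unchanged groups. Both comparisons share the 3 DMSO arrays, which are too few to be split. In the simulations r averaged 0.45 and ran from -0.61 to 0.95, and the covariance was 0.023 against a simulated 0.016 (SD 0.018), so a shared response across all probe sets was not detectable by these measures. When each array was left out in turn, r was 0.52 to 0.75 and the overlap 2 to 5, with 5 without DMSO replicate 2 and 4 without DMSO replicate 3.

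**Figure D2:**
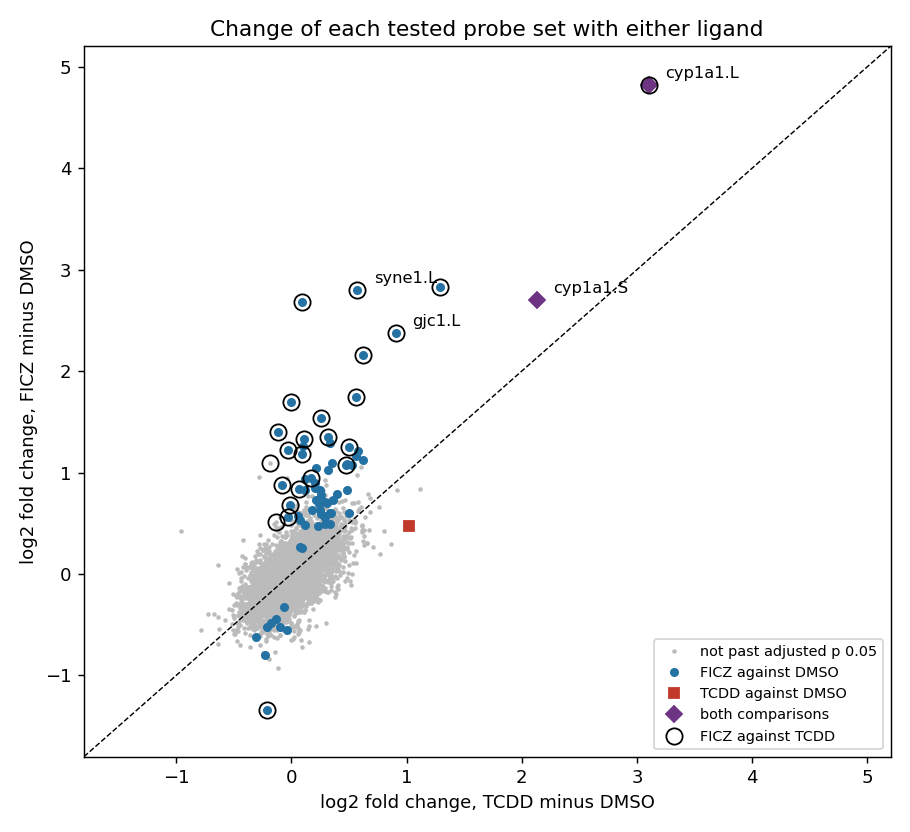
Log2 change with TCDD on the horizontal axis and with FICZ on the vertical axis, each against DMSO, for 11618 tested probe sets. Colors mark probe sets past an adjusted p of 0.05 against DMSO, open rings mark the 24 that differed between FICZ and TCDD, and the dashed line marks equal change; all 61 that rose with FICZ lie above that line.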

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

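The test for a common factor, the tests with held-out pairs of arrays and under other normalizations, and the counts over other splits were chosen only after the result was seen; the counts without single arrays were set before. The response differed between the ligands in 24 probe sets by a direct test of FICZ against TCDD, 23 higher with FICZ.

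A single ligand array as the source of that difference is argued against by arrays that took no part in the choice of probe sets. For each of the 9 pairs of 1 FICZ and 1 TCDD array, the 24 probe sets with the smallest p without that pair were chosen anew. In the held-out pair at least 20 of the 24 kept their sign, the fewest with FICZ replicate 1 and TCDD replicate 1, and the median difference was 0.66 to 1.22 times that in the other arrays. The test, set after the result was seen, asked for at least 20, so the lowest count only just met it. Without the pair, 4 to 12 of the 24 chosen passed the adjusted threshold by limma, so this is a check of sign and size and not of calls. Fewer passed the adjusted threshold when 1 array was left out (14, 11 and 15 without FICZ replicates 1, 2 and 3, 14 without TCDD replicate 2 and 13 without TCDD replicate 3). Of the 24, 16 passed the adjusted threshold with the values as deposited, 24 with median centring and 23 with cyclic loess. The lowest of these, 16, lies between the bounds of 12 and 20 set for the test, so the normalization as a source for part of the 24 is left open. The 8 that lost the call had a median log2 difference of 0.89 (SE 0.15) before and 0.88 (SE 0.17) with the values as deposited, so that a larger error and not a smaller difference went with the loss. Whether TCDD gave the FICZ response scaled down by 1 factor or a response of another makeup cannot be told apart here. With a common factor of 0.38, 6 of 71 called probe sets (8.45%) deviated, between the bounds of 5% and 10% set for the test. Simulated scaled copies gave a median of 1.45% and at most 5.97%, so the share lay above all 100 of them. Their noise was independent between probe sets, unlike that of these arrays, so they cannot decide the question. With the factor of 0.27 found without cyp1a1, 4 deviated. A difference in how the ligands act within 3 h, for example in potency at the shared dose, may underlie the 24 and stays open as untested, since each ligand was given at 1 dose and 1 time. No protocol states which arrays shared a day or culture. A difference of that kind between the groups therefore cannot be told apart from the ligand, in these calls or in those against DMSO.

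For the comparisons of 3 against 3 arrays the 10 possible splits are too few for a share under 0.05. The real split gave 70 for FICZ against DMSO and the highest other split 0, with 1 split giving as many. For FICZ against TCDD the real split gave 24 and the highest other 0, again with 1 split giving as many. For TCDD against DMSO the real split gave 3 and the highest other 29, so that 2 splits gave as many. The split with 29 set DMSO replicates 1 and 3 and TCDD replicate 1 against the rest, which points to a structure of the samples other than the treatment. For both ligands against DMSO, 3 of 100 splits, the real one with 26 included, gave as many. That share is under 0.05. The splits set against the real one were drawn at random from a larger number, so the share is uncertain and argues only weakly against chance. The highest other gave 62 and set the 3 FICZ arrays against the rest, and a further split with DMSO replicates 1 and 3 and TCDD replicate 1 as the control group gave 45, although another division of the other 6 arrays against the same control group gave 0.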

How the results depend on the processing

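Array weights and leaving out the second DMSO and second FICZ arrays together were chosen only after the data were seen; the other alternatives were planned. No called probe set reversed its direction in the 19 refits in which it was tested. That outcome was largely fixed in advance and says little. Other filters, other variance priors and the replicate block leave the log2 changes as they are. Most called probe sets also had no overlap between arrays. The camera direction of the respiratory chain list turned to lower, without passing, when DMSO replicate 2 was left out (adjusted p 0.60 with TCDD against DMSO and 0.81 with both ligands against DMSO) and when both arrays were (0.58 and 0.90). Counts of called probe sets are given in the order TCDD against DMSO (3), FICZ against DMSO (70), FICZ against TCDD (24) and both ligands against DMSO (26). Median centring (4, 74, 25, 28), cyclic loess (4, 71, 23, 27), no filter (3, 65, 23, 20), a filter at the 50th percentile (3, 54, 18, 18) and a robust prior (4, 75, 24, 28) kept all within 1.5 times, and values as deposited gave 3, 56, 16 and 14. eBayes without the trend gave 1, 40, 8 and 16, array weights 22, 154, 355 and 105, and the per-probe-set test without a shared variance prior 0, 0, 1 and 0, that test having fewer degrees of freedom. A minimum of 2-fold gave 28 for FICZ and 8 for both ligands, by its construction. Both arrays left out gave 43 for FICZ against DMSO, of which 35 were among the 70. For TCDD against DMSO they gave 3, of which 2 were among the 3 of the main fit. Fitting only the groups compared gave 40 for FICZ against TCDD. Leaving out each array gave 3 to 7, 26 to 80, 11 to 41 and 13 to 35. Except where stated, the cause was not tested. Pseudocount alternatives were not run, as the values were already logged.

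Lists past the camera threshold (4, 5, 3, 5) came to 0, 0, 0 and 0 with an estimated correlation, 0, 1, 0 and 1 with fry, 9 for TCDD and 9 for both ligands with values as deposited, and 0 for FICZ against TCDD without a filter. Leaving out each array gave 4 to 10, 5 to 8, 0 to 8 and 4 to 9. The overlap of the responses (2) was 4 at an adjusted p of 0.10 and 2 to 5 without each array, and the correlation of their changes was 0.53 without a filter and 0.52 to 0.75 without each array. Of 59 calls singled out in the text, 47 on named genes and 12 on probe sets without a single name, 43 held with values as deposited and 59 with array weights, and 247 of 396 held over the fits without each array. The array weights were 9 for TCDD replicate 3 and 0.4 and 1.28 for the other TCDD arrays. The weighted TCDD mean thus leaned on 1 array, and calls and counts with these weights say little about robustness. Without detection calls, the limit that background sets on dim probe sets is unknown.

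With a replicate block, which takes equal title numbers as pairs, 4, 88, 28 and 27 probe sets and 5, 5, 4 and 6 lists passed. The pairing has no basis in the protocols, so the numbers were treated as names. Residuals of arrays with equal numbers correlated at 0.48, 0.27 and 0.00 for DMSO and TCDD, and those with unequal numbers at -0.36 to 0.25. For DMSO and FICZ equal numbers gave -0.14, -0.01 and -0.05, and unequal ones -0.09 to 0.18. For TCDD and FICZ they gave -0.27, -0.06 and 0.00, and -0.15 to 0.21. These values do not exclude a pairing of DMSO with TCDD arrays, and the FICZ numbers of the descriptions were not tried.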

Other observations

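The tests of replication against mitotic genes, those without single arrays and under other normalizations included, were chosen only after the called genes were seen; the heme test was set before its result. Within the cell cycle list, genes of DNA replication and genes of mitosis were set apart. With FICZ against DMSO, 26 of 34 replication genes had negative changes (median -0.17), and 14 of 36 mitotic genes did (median 0.02). The replication genes with the smallest p values were mcm10.L (-0.62), mcm5.L (-0.52), cdc6.L (-0.57), cdc6.S (-0.53) and mcm2.L (-0.30), which act in the start of replication, and of which mcm10.L and mcm5.L passed over all genes. cdc6.S and mcm2.L fall outside the rule for named genes and were chosen after their values were seen. Among mitotic genes, cdk1.L changed by 0.13 and plk1.S by -0.05, and neither passed. With TCDD against DMSO the replication genes had a median of -0.07 and a fry p of 0.13, and the mitotic genes, 24 of 36 with negative changes, a median of -0.05 and a fry p of 0.42. With FICZ against TCDD the replication genes had a median of -0.09 and a fry p of 0.0038, and the mitotic genes, 32 of 36 with positive changes, a median of 0.09 and a fry p of 0.21.

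A lower level of replication genes apart from mitotic genes may be part of the FICZ response. camera over both lists alone, with an estimated correlation, put the replication genes lower at an unadjusted p = 0.0089. Without the 5 genes seen beforehand, camera with an estimated correlation put the other 29 lower at an unadjusted p = 0.021. fry gave p = 0.00079 for the replication genes and p = 0.63 for the mitotic genes, but with the values as deposited the fry p was 0.030 over the 34 and 0.11 over the 29, and with median centring 0.104 over the 29. Whether a single array or the normalization is the source cannot be told apart from a response to FICZ. When each of the 6 arrays was left out, camera with an estimated correlation over all 34 genes stayed under 0.05 (p = 0.049 at the highest), whereas over the 29 it did not without DMSO replicate 1 (p = 0.097) or DMSO replicate 3 (p = 0.101). With the values as deposited camera with an estimated correlation gave p = 0.054 over the 34 and p = 0.083 over the 29, with median centring p = 0.034 and p = 0.054, and with cyclic loess p = 0.0071 and p = 0.017. The replication genes stood lower in each of these refits. Over the 29, their median less that of the mitotic genes was -0.17, and it was -0.18 without DMSO replicate 1 and -0.21 without DMSO replicate 3. It was -0.15 with the values as deposited. Median centring shifts all probe sets of an array by the same amount, so its -0.15 was fixed by the deposited values and is no further check. The difference did not shrink as the test, set after the result was seen, asks of either source. The lost calls therefore do not speak for these sources. The pattern was found and tested on the same arrays and stays open, and no measure of cell number or cell cycle phase was used here.

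alas1.S rose with FICZ against DMSO by 0.84 on the log2 scale (adjusted p 0.00025), and its copy alas1.L changed by 0.26 and did not pass (adjusted p 0.70). A rise of the whole heme synthesis pathway could have accompanied it. The other measured genes, alad.S (0.10), urod.L (-0.02), ppox.L (0.11) and fech.L (-0.11), gave a directional fry p of 0.77. Their mean change was 0.02 (95% confidence interval -0.16 to 0.21), which excludes a rise of the size of alas1.S but not a small one.

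Chance list calls were frequent in experiments simulated without any change but with the correlated noise of these arrays. In the order TCDD against DMSO, FICZ against DMSO, FICZ against TCDD and both ligands against DMSO, 86, 91, 86 and 93 of 100 such experiments had at least 1 list past the camera threshold at the preset correlation. As many lists as in the data (4, 5, 3 and 5) were reached in 47, 42, 55 and 41 of them. The median number of called probe sets in these experiments was 0 in each comparison.

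Among the arrays, DMSO replicate 2 lay at 29.9 on the first principal component (30.6% of variance) and had an array weight of 0.18, the lowest of 9, while TCDD replicate 3 had a weight of 9. FICZ replicate 2 lay at 20 on the second component (17.4%), had 52 probe sets at the floor and the lowest median, 6.67. Of the 120 control probe sets, 0 passed by limma on the values as deposited in each comparison, with 2, 14, 2 and 8 at an unadjusted p under 0.05. The 14 for FICZ against DMSO and the 8 for both ligands exceed a chance share of 0.05. The mean log2 signal of 9 hybridization spikes was 9.48, 9.80 and 9.35 on the DMSO arrays, 9.79, 9.83 and 9.91 on the FICZ arrays and 9.72, 9.57 and 9.81 on the TCDD arrays.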
